A study of Mus musculus with 6 samples.

How the data were processed

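Total RNA from mouse tongues at embryonic day 14.5 (strain C57BL/6J) was measured on 6 Affymetrix expression arrays with biotin-labelled cRNA, per the labels' protocols. The samples were 3 mutants with Tgfbr2 floxed on both chromosomes and Wnt1-Cre, and 3 controls with the floxed alleles and no Cre. The titles call the controls Tgfbr2 wildtype. The deposited table holds 1 value per probe set and array. The authors made these log2 values with RMA (background correction, quantile normalization and summary of the probes of a probe set), per the submitters' processing notes, which give no version. The values of each array lay between 2.53 and 14.93 and the array medians between 5.924 and 5.983, as log2 values would. RMA compresses differences of dim probe sets, and its quantile step gives all arrays nearly the same distribution, so a change shared by most genes would not show. Arrays have no read depth: the number of arrays limits the precision, and dim probe sets lie close to the background.

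The table holds 45101 probe sets, of which 64 are control probe sets. In the platform annotation used here, 34945 have 1 gene symbol, 932 have several and 9160 have none listed. The symbols were compared through Entrez identifiers with a RefSeq gene table of the assembly GRCm38.p6, which changed 0 symbols and held no match for 204 probe sets. Only probe sets with 1 gene were named. They read 18193 genes, 9010 of them with several probe sets, and the probe set with the highest mean over all 6 arrays stood for a gene. Genes whose mean lay in the lowest 25% (under 5.17 on the log2 scale) were left out, which left 13645 genes. Of the called genes, 109 had another probe set above that value, 160 probe sets in all: 150 had the same sign, and 0 had the opposite sign with an unadjusted p under 0.05. The probe set names of 28 called genes end in a suffix that marks probes shared with similar transcripts, so these can read relatives too. Among the called genes named below, these include C1s1, Aspn, Dsp, Dmp1, Smyd1, Rrm2, Ndrg1 and Fmod.

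Mutants and controls were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting, 2-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists that had at least 5 tested genes. The 27 lists, 543 distinct genes in all with 6 held by more than 1 list, name muscle, connective tissue, signalling, stress and other cell types that a tongue sample could hold. Of their genes, 27 have no probe set with a single gene name and were not analysed here. Counts adjusted over the list alone repeat the adjustment within the list. A list's median is taken over the log2 differences of its genes, and per array over the values relative to the control mean of each gene. Principal components and Pearson correlations were computed over the tested genes. Figures were drawn with matplotlib 3.10.9.

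The groups, the test, the lists and the rule for the genes named were fixed before the data were examined. The rule names Tgfbr2, the 10 highest and the 10 lowest log2 fold changes among called genes whose groups do not overlap (clone-type names left out), up to 4 members of each list with the smallest p, and 13 genes of muscle, tendon, FGF and TGF-beta biology whatever their result. Genes outside the rule are said to be named after their values were seen. The alternatives fixed at the same time were no filter, the lowest 50% of genes left out, the mean of a gene's probe sets or every probe set on its own, arrays centred on their median, a further quantile normalization, eBayes with trend and robust fitting, array quality weights, the replicate number as a block, each array left out in turn, a fold of at least 1.5, an adjusted p under 0.1, and for the lists the estimated correlation, fry and shared genes left out. Added after the data were seen were sex as a covariate, from Xist and the Y-linked genes, the estimated correlation without mutant array 1, and fry without each array.

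The titles number the arrays 1 to 3 in both groups, and no label says what a number stands for. Over the tested genes, the deviations of same-numbered mutant and control arrays from their group means correlated at 0.309, 0.105 and 0.206, all over the limit of 0.1, so by the rule set beforehand the numbers were taken to pair the arrays. This pairing rests on the title numbers and these correlations alone. Deviations cancel within each group, so the 3 correlations are not independent of each other. The unlike-numbered pairs of arrays 2 and 3 correlated at 0.147 and 0.196, both above the 0.105 of the arrays numbered 2. The main fit was fixed beforehand without a block, so the calls and counts given first ignore this pairing. The fit with the block is given beside a result where it changes the call or moves a count by more than 1.5 times.

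The steps were tested on 5 simulated data sets of the 13645 genes, each with 200 genes changed. The spread of each gene was the one moderated by eBayes, the same in both groups. The fit called 30.8% of the genes changed by 0.5 on the log2 scale, 94.4% at 1, 99.6% at 1.5 and 100% at 2, and 4.6% of its calls were unchanged genes. A list lowered by 0.5 was called in 5 of 5 data sets, with the preset and with the estimated correlation, and 2 other lists were called over all data sets. In these simulations genes vary independently, so they say nothing about lists whose genes vary together. They hold no array that stands apart, so the shares called may be too favourable for the real arrays.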

Results

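Tongues of mouse embryos were profiled at embryonic day 14.5 on 6 Affymetrix arrays, 3 from mutants and 3 from controls. In the mutants both floxed copies of Tgfbr2, which encodes the type II receptor for TGF-beta, were exposed to Wnt1-Cre, a recombinase active in the neural crest and its descendants. The controls carried the floxed copies without Cre, although their titles call them Tgfbr2 wildtype. In the tongue, the neural crest gives rise to most of the connective tissue, whereas the skeletal muscle fibres come from mesoderm and keep an intact receptor gene in this design. The series asked which genes depend on TGF-beta receptor signalling in the neural crest while tongue muscle forms, given that the mutants have an abnormally small tongue. The labels describe the material both as tongue and as tongue mesenchyme, and they do not say whether the arrays come from separate litters, so the p-values measure the spread between these samples. Values are log2 expression, 13645 genes were tested, and the 3 arrays per group limit the precision: the median standard error of a log2 difference was 0.117.

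On the first principal component the arrays separated by genotype, but mutant array 1 lay apart from all the others. The first principal component held 57.2% of the variance and placed mutant array 1 at -39.1, mutant arrays 2 and 3 at -6.91 and -2.87, and the controls between 9.29 and 20. The second component, with 22.6%, put mutant arrays 2 and 3 at -21.5 and -13.2 and the other 4 arrays above 0. Pearson correlations over genes were 0.9935 to 0.9976 among the controls, 0.9924 between mutant arrays 2 and 3, and 0.9658 to 0.9782 between mutant array 1 and the rest. Mutant arrays 2 and 3 correlated with the controls at 0.9841 to 0.9892, more closely than with mutant array 1 (0.9775 and 0.9782). The sex-linked genes followed neither genotype. Xist, the RNA of the inactive X chromosome, was between 11.7 and 13.2 in mutant arrays 1 and 3 and control array 1, where the Y-linked genes Eif2s3y, Kdm5d and Uty were between 2.90 and 3.34. In mutant array 2 and control arrays 2 and 3, Xist was between 6.14 and 6.43 and the Y-linked genes were between 7.84 and 9.44. These sex-linked genes were described and not tested as a list, because only 4 of the 5 members were measured.

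**Figure D1:**
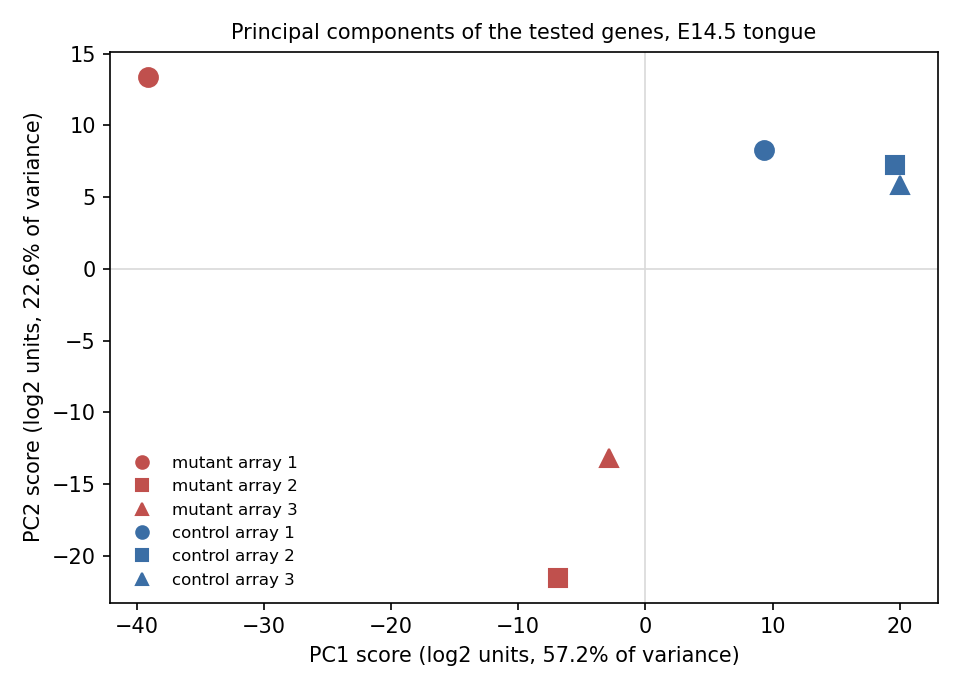
Scores of the 6 arrays on the first and second principal components of the tested genes (log2 units; 57.2% and 22.6% of the variance), with colour for genotype and marker shape for the replicate number. The 3 control arrays lie between 9.29 and 20 on the first component, and mutant array 1 lies at -39.1.

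Tgfbr2 RNA itself did not pass the threshold between the genotypes on any of its 3 probe sets. The brightest gave 11.55 ± 0.34 (SD, n = 3) in the mutants and 11.73 ± 0.15 (SD, n = 3) in the controls, a log2 difference of -0.18 (standard error 0.18, adjusted p = 0.642). The other probe sets differed by -0.145 and -0.044. Without mutant array 1 the difference of the brightest was 0.014 (adjusted p = 0.957). Which part of the gene the recombination removes, and whether any probe lies in it, is not given in the sources used here, and cells outside the neural crest keep the gene, so these values do not test the genotype labels.

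Between mutants and controls, 292 genes differed at an adjusted p under 0.05 (limma), 180 higher and 112 lower in the mutants. This balance depended on the scaling and on single arrays: 149 of 276 were higher with arrays centred on their median, 43 of 88 without mutant array 2, 121 of 242 without mutant array 3, 73 of 142 without control array 1 and 10 of 19 without control array 3, against 433 of 670 without mutant array 1 and 10 of 16 without control array 2. The highest fitted log2 differences were those of Gt(ROSA)26Sor, a widely expressed noncoding locus, by 3.55, Vit, encoding the matrix protein vitrin, by 3.10, and Scara5, encoding a ferritin receptor of stromal cells, by 2.83. The controls had Gt(ROSA)26Sor at 4.53 and Vit at 5.05, under the filter value of 5.17, where RMA compresses differences, so the sizes and the order of these increases are uncertain. The largest decreases were those of Fgf6, a growth factor gene expressed in developing skeletal muscle, which fell by 2.83 (7.11-fold), Fabp4, encoding a fatty acid binding protein of fat cells, capillaries and macrophages, which fell by 2.73, and Col19a1, encoding a collagen expressed in embryonic muscle, which fell by 2.52. All 292 had 3 mutant values on one side of the 3 control values, as had 25.1% of all tested genes, where chance gives 10%. The fold was at least 1.5 for 261 of them, and 2305 genes had an unadjusted p under 0.05. The count depended on single arrays: it was 670 without mutant array 1 (291 of the 292 among them, all 292 with the same sign), 88 without mutant array 2, 242 without mutant array 3, 142 without control array 1, 16 without control array 2 and 19 without control array 3. Of the 55 called genes that the naming rule picked, 45 lost the call without control array 2 and likewise without control array 3. With the replicate number as a block the count was 490 (283 higher, 276 shared), and with sex as a covariate, an alternative added after the data were seen, it was 135 (128 shared). Of the 55 named calls 23 were lost with that covariate (adjusted p between 0.0519 and 0.126): those of Gt(ROSA)26Sor, Sned1, Atp1b4, Msc, Meox1, Smyd1, Nrap, Dcn, Junb, Grem1, Wnt10a, Rrm2, Dsp, Pkp1, Col9a1, Dmp1, C1qb, C1qc, Egfl8, Stmn2, Egr2, Slc2a1 and Bbc3. The log2 differences of these 23 with the covariate were 0.894 to 1.08 times those without it (0.863 to 1.14 times for all 292), so the losses do not show that the changes were due to sex.

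Some named genes without a call passed under an alternative. With array quality weights 37 passed (adjusted p between 0.00233 and 0.0417): Barx1, Bmp5, Casq1, Ccna2, Ccne1, Cdh19, Cldn5, Dcx, Dlx2, Egr1, Eln, Eya2, Fabp7, Fas, Fgfr2, Gli1, Hhip, Id4, Igfbp3, Kif11, Krt14, Krt15, Musk, Myf6, Myl1, Nefl, Nefm, Notum, Phlda3, Rspo1, S100b, Slc4a1, Smad6, Spry1, Tfap2b, Tgfbi and Wnt4. The number was 21 when mutant array 1 was left out (between 0.00175 and 0.0484): Bmp5, Cdh19, Cldn5, Dcx, Egr1, Eya2, Fabp7, Gli1, Hhip, Kif11, Krt14, Krt15, Musk, Nefm, Phlda3, Rspo1, Slc4a1, Tfap2b, Tgfbi, Tgfbr3 and Wnt4. As means of their probe sets 11 passed (between 0.00671 and 0.0497): Bmp5, Ccne1, Cldn5, Dcx, Eya2, Fabp7, Fgf4, Id4, Krt15, Nefl and Phlda3. Casq1, Myf6, Nefl and Nefm passed without control array 1 (between 0.0119 and 0.0408), and Bnip3, Fgfr2, Krt14 and Krt15 without mutant array 3 (between 0.0204 and 0.0388). Krt15 passed with trend and robust fitting (0.0386), and with quantile normalization Eya2 (0.0407) and, barely, Fabp7 did. The 20 that passed with the replicate block (between 0.00887 and 0.0472) are given with their values below.

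Among the 10 strongest increases, Vit went from 5.05 ± 0.33 to 8.16 ± 0.42 and Scara5 from 7.68 ± 0.064 to 10.51 ± 0.48 (SD, n = 3 per genotype), each with an adjusted p of 0.00320. Pmaip1, which encodes the pro-apoptotic protein Noxa, was 2.64 higher (standard error 0.18, adjusted p = 0.00298). Shisa3, which encodes an inhibitor of Wnt and FGF receptors, was 2.57 higher (standard error 0.19), and Fam162b was 2.77 higher (standard error 0.24). Igfbp1, an insulin-like growth factor binding protein gene, rose by 2.67, Cxcl13, a B cell chemokine gene, by 2.53, Sned1, a matrix protein gene, by 2.09, and C1s1, a complement protease gene, by 2.07. Gt(ROSA)26Sor had the widest spread among the mutants, with values of 9.69, 6.98 and 7.57 in mutant arrays 1, 2 and 3 against 4.53 ± 0.25 in the controls. Its adjusted p was 0.0359, and its log2 difference was 2.74 without mutant array 1. Scara5 has another, dim probe set, which differed by -0.072, and the mean of its probe sets gave 1.38. Further probe sets of Cxcl13 and Shisa3 gave 1.48 and 2.28, the latter from a control mean of 4.52.

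Among the 10 strongest decreases, Fgf6 went from 8.62 ± 0.17 to 5.79 ± 0.22 (SD, n = 3 per genotype, adjusted p = 0.00154). Fgf5, another FGF gene, went from 6.46 ± 0.24 to 4.23 ± 0.21, and Angptl1, encoding a secreted angiopoietin-like protein, from 11.44 ± 0.11 to 9.32 ± 0.19. Genes of muscle were among the strongest decreases: Ankrd1, a stretch-responsive muscle ankyrin repeat gene, fell by 2.33 (standard error 0.24), and Atp1b4, which encodes a muscle protein of the inner nuclear membrane, fell by 2.13 (standard error 0.37). The log2 differences of Prokr2, a prokineticin receptor gene, Calcb, a calcitonin gene-related peptide gene, and Lyve1, a marker of lymphatic endothelium and of tissue macrophages, were -2.40, -2.23 and -2.21. The mutant means of Fgf5, Calcb (4.44) and Lyve1 (4.58) lay under the filter value of 5.17, so the sizes of these 3 decreases are uncertain too. Further probe sets of Fabp4, Col19a1, Angptl1, Prokr2 and Ankrd1 gave -2.54, -2.82, -1.92, -2.07 and -2.42. A further, dimmer probe set of Lyve1 gave -0.80, with means of 5.33 in the controls and 4.54 in the mutants. Other, mostly dim probe sets of Fabp4, Col19a1, Angptl1 and Fgf5 gave values between -0.205 and 0.060. The means over the probe sets of Fabp4, Fgf5 and Angptl1 were -1.34, -1.22 and -1.33, and these genes passed with them. Of these 20 leading genes, 9 passed in each of the 6 fits that left out 1 array (Vit, Scara5, Fam162b, Pmaip1, Shisa3, Fgf6, Prokr2, Fgf5 and Angptl1), and the other 11 lost the call without control array 2 and without control array 3. With the sex covariate 3 of the 20 lost it: Gt(ROSA)26Sor (adjusted p = 0.0693), Sned1 (0.0697) and Atp1b4 (0.0766).

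**Figure D2:**
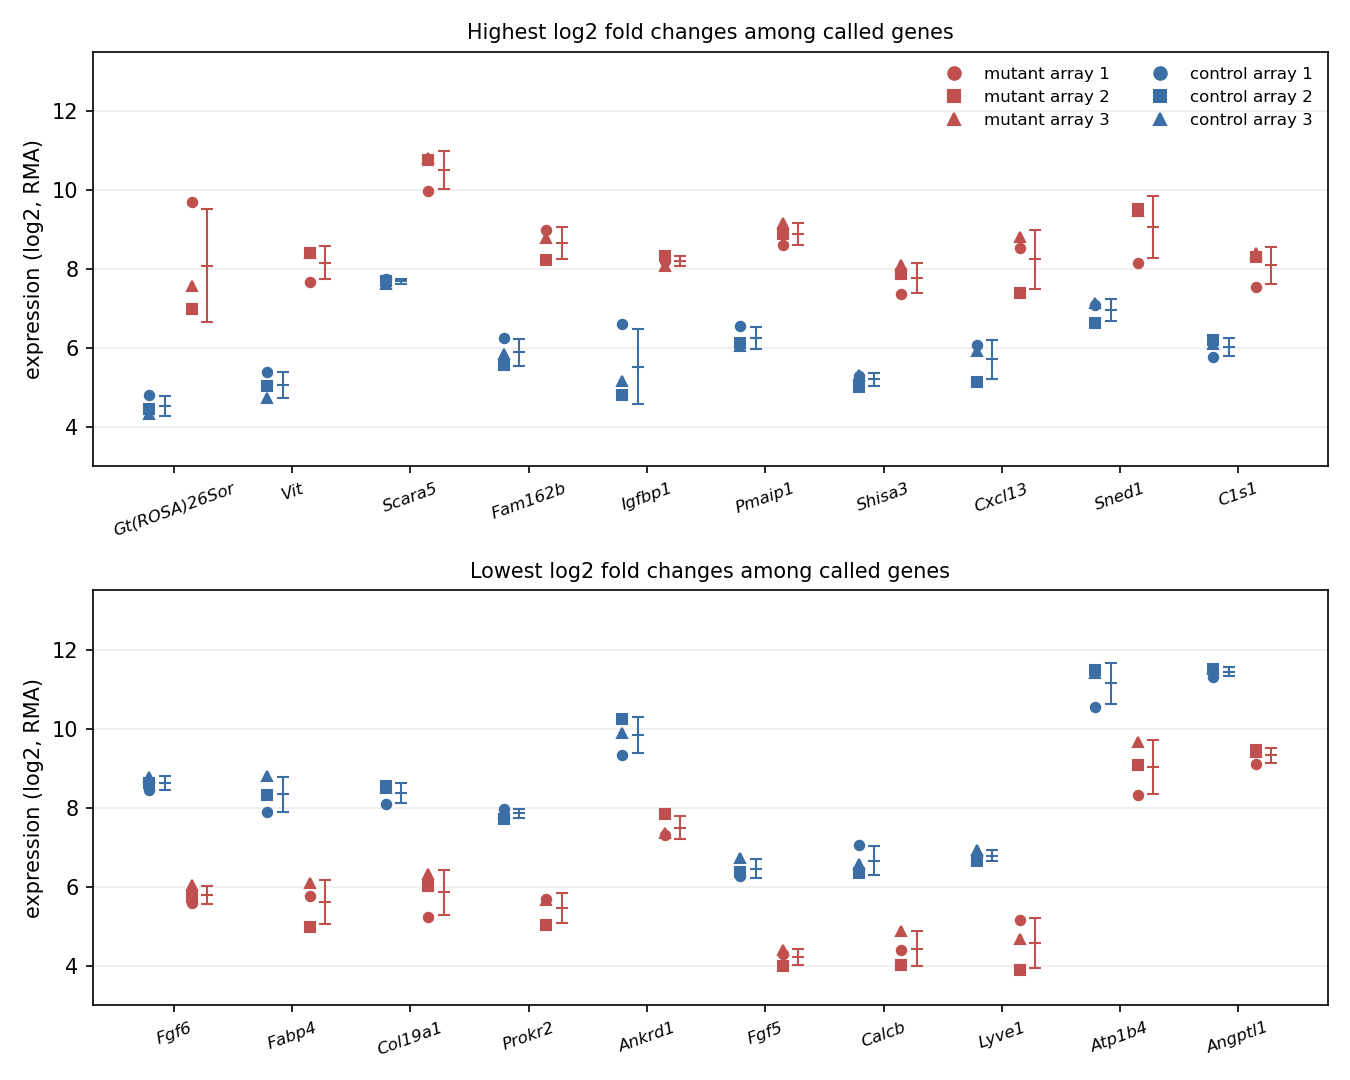
Log2 expression of the 10 genes with the highest and the 10 with the lowest log2 fold changes among those past the threshold, for each array (points, marker shape by replicate number) with the mean and SD of each genotype (bars, n = 3). For every gene shown the 3 mutant values lie on one side of the 3 control values, for example 5.79 ± 0.22 against 8.62 ± 0.17 for Fgf6.

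Most genes of the contractile apparatus had lower values in the mutants. Of 38 tested sarcomere genes 34 had a negative log2 difference, with a median of -0.625, and 3 passed on their own: Actn3, encoding the fast-fibre alpha-actinin (-1.68, standard error 0.20, adjusted p = 0.0105), Nrap, encoding a protein of myofibril assembly (-1.63, standard error 0.31, adjusted p = 0.0476), and Smyd1, encoding a myosin-modifying methyltransferase (-0.55, standard error 0.10, adjusted p = 0.0470). The Smyd1 call rested on the probe set used: the mean of its probe sets gave -0.18 (adjusted p = 0.271), and the call was also lost with the lowest 50% of genes left out (0.0543), with trend and robust fitting (0.0519) and with every probe set tested on its own (0.0602). Nrap lost it with the lowest 50% left out (0.0569), with quantile normalization (0.0512) and with every probe set tested on its own (0.0601). Adjusted over the list alone, 20 were lower and 1 was higher. The list shifted down with camera's preset correlation of 0.01 (adjusted p = 1.11e-12). It did not with the correlation estimated from these arrays, which was 0.427, far above the preset (adjusted p = 0.382 with an estimated correlation). Of the 30 tested genes of muscle excitation, neuromuscular junction, fusion and energy supply, 27 were negative, with a median of -0.45 (-0.29 without mutant array 1). Pgam2, the muscle phosphoglycerate mutase gene, fell by 0.72 (adjusted p = 0.0103), whereas Mb, encoding the oxygen-binding protein myoglobin, rose by 0.94 (adjusted p = 0.0154), or by 0.47 as the mean of its probe sets. Those were the only 2 calls (1 higher and 3 lower without mutant array 1), against 5 lower and 1 higher adjusted over the list alone, and this list too shifted down with the preset correlation (adjusted p = 8.82e-09) but not with the estimated one (adjusted p = 0.382 with an estimated correlation). Casq1, the calcium store gene of the sarcoplasmic reticulum, gave -1.53 (adjusted p = 0.0621, 0.0191 with the block), and Myl1, a fast myosin light chain gene, gave -0.55 (0.0906, 0.0386 with the block). The sarcomere medians per array were -0.82, -0.51 and -0.32 in mutant arrays 1, 2 and 3 and -0.21, 0.10 and 0.098 in the controls. Without mutant array 1 the median difference was -0.455. Embryonic myosin, Myh3, was very bright and differed by -0.69 (adjusted p = 0.325, -0.29 without mutant array 1).

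The transcription factors that commit and differentiate muscle cells did not pass on their own. Myod1 differed by -0.42 (adjusted p = 0.390), Myog by -0.19 (0.409), Myf5 by 0.27 (0.288), Pax7, the marker of muscle progenitors, by -0.47 (0.428), and Myf6 by -0.83 with an adjusted p of 0.0682. With mutant array 1 left out, Myod1, Myog and Pax7 differed by -0.17, -0.100 and -0.12. Of the 19 tested myogenic regulators 2 passed, both lower: Msc, a muscle bHLH repressor gene (fell by 0.66, adjusted p = 0.0188), and Meox1, a homeobox gene of somites (fell by 0.78, adjusted p = 0.0387). Without mutant array 1, 1 was higher and 3 were lower, and adjusted over the list alone 5 were lower and 1 was higher. Eya2, a cofactor gene of homeobox proteins, gave 0.53 (adjusted p = 0.0548). The list shifted down with the preset correlation (median -0.205, adjusted p = 0.000442), and that call was lost without mutant array 1 (median -0.100, adjusted p = 0.0596) and with an estimated correlation (adjusted p = 0.443). Mutant array 1 had a median of -0.62 for these genes, and mutant arrays 2 and 3 had -0.073 and -0.065.

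Connective tissue genes moved in both directions. Of 16 tendon and connective tissue genes 6 were lower and 2 higher (8 and 2 adjusted over the list alone). Aspn, encoding asporin, an inhibitor of TGF-beta, fell by 2.08 (adjusted p = 0.0187) and Thbs2, encoding thrombospondin 2, by 1.39 (adjusted p = 0.0177). The small proteoglycan genes Lum and Dcn rose by 0.77 and 0.65 (adjusted p = 0.0152 and 0.0238), and Dcn lost the call as the mean of its probe sets (0.41, adjusted p = 0.0589). The other 4 lower calls, named here after their values were seen, were Tnc (-1.94), Fmod (-0.95), Ogn (-0.81) and Kera (-0.75), the last with an adjusted p of 0.0529 with the block. Of these 4, Tnc, Ogn and Kera lost the call with the sex covariate (adjusted p = 0.0659, 0.0761 and 0.0811). Scx, the tendon transcription factor gene, differed by -0.33 (adjusted p = 0.187). The list's median was -0.44 (adjusted p = 0.000468 with the preset, 0.382 with an estimated correlation), and -0.27 without mutant array 1. Of 22 fibrillar and elastic matrix genes 2 passed, over all genes and adjusted over the list alone: Fbln5 and Mfap4, both genes of elastic fibre assembly, were lower, with log2 differences of -1.99 and -1.35 (adjusted p = 0.00772 and 0.0214). The mean of the Fbln5 probe sets gave -1.05. Eln, encoding elastin, gave -0.78 (adjusted p = 0.158, 0.0458 with the block) and Fn1, encoding fibronectin, gave -1.11 (0.232, 0.0125 with the block), against -0.49 and -0.66 without mutant array 1. The matrix list's median was -0.34 (adjusted p = 6.98e-05 with the preset correlation of 0.01, 0.574 with an estimated correlation of 0.787). It rested on mutant array 1, whose median was -1.04 against 0.025 and -0.059 in mutant arrays 2 and 3. Without that array the median was -0.023 and the adjusted p 0.110.

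With all arrays none of 25 tested components of the TGF-beta pathway passed, over all genes or adjusted over the list alone (limma, adjusted p of the list 0.820 with camera and 0.991 with fry). With mutant array 1 left out, fry called the list higher (adjusted p = 0.0422), whereas camera did not (0.170), and 1 component passed, the receptor gene Tgfbr3. With all arrays the ligand gene Tgfb2 differed by -0.063, the receptor genes Tgfbr1 and Tgfbr3 by -0.012 and 0.20, and the inhibitor Smad6 by 0.54 (adjusted p = 0.124). Other, dimmer probe sets of Tgfbr1 gave -0.50 and -0.195 and did not pass (adjusted p = 0.32 and 0.506 over all probe sets). Without mutant array 1 Tgfbr3 differed by 0.60 with an adjusted p of 0.0186, against 0.30 (0.269) for Tgfb2. The ligand gene Tgfb3 gave -0.56 (adjusted p = 0.223, 0.0472 with the block), and -0.34 without mutant array 1. Of 21 genes that TGF-beta is known to induce, 2 passed and both were higher: Cdkn2b, a cell cycle inhibitor gene, by 1.05 (adjusted p = 0.0150) and Junb by 0.64 (adjusted p = 0.0354), from a control mean of 4.92, under the filter value of 5.17. Without mutant array 1, 6 were higher and 1 lower, and adjusted over the list alone 5 were higher and 2 lower. Tgfbi, whose product is a matrix protein, gave -1.62 (adjusted p = 0.0618, 0.0211 with the block, 0.00175 without mutant array 1), and Igfbp3 gave -0.60 (0.0866, 0.0457 with the block). The list did not pass with camera (adjusted p = 0.672, 0.179 without mutant array 1) or with fry (0.412), but fry called it higher without mutant array 1 (0.0236). With all arrays its median (-0.060) and mean (0.0575) differed in sign, and the median was 0.045 without mutant array 1.

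In FGF signalling 2 of 22 tested members passed, the ligand genes Fgf6 and Fgf5, against 3 lower and 1 higher adjusted over the list alone. Fgf10, a mesenchymal ligand gene, differed by 0.17 (adjusted p = 0.653). The probe sets of Fgf4 disagreed. The brightest, which stood for the gene, differed by 0.0855 (adjusted p = 0.703), and the next went from 5.55 to 4.34 and from 5.20 to 4.46, log2 differences of -1.21 and -0.74 (adjusted p = 0.00961 and 0.0430 over all probe sets), at levels near the filter value of 5.17. The mean of the Fgf4 probe sets was lower in the mutants, with a log2 difference of -0.50, and passed (adjusted p = 0.0206). The list's camera test gave an adjusted p of 0.0615, 0.0436 with the block, 0.0364 without mutant array 3, 0.0310 without control array 1 and 0.0136 when each gene was the mean of its probe sets. It gave 0.421 with an estimated correlation. Spry1, a feedback inhibitor of FGF receptors, gave -0.40 (adjusted p = 0.0769) and Fgfr2 gave 0.64 (0.0996).

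With all arrays none of the other signalling lists passed. In BMP signalling Fst, encoding follistatin, an antagonist of activins and myostatin, rose by 1.37 (standard error 0.11, adjusted p = 0.00361), and Grem1, a BMP antagonist gene, fell by 0.59 (adjusted p = 0.0298). The remaining 18 of 20 members did not pass (4 higher and 2 lower adjusted over the list alone, adjusted p of the list 0.824). Without mutant array 1, 1 BMP gene was higher and 2 were lower. When mutant array 1 was left out, fry called the BMP list and the Notch list higher (adjusted p = 0.0422 for each), whereas camera did not (0.475 and 0.254). Bmp5 gave -0.86 (adjusted p = 0.0908, 0.0127 with the block). In Wnt signalling Wnt10a rose by 0.90 (adjusted p = 0.0298) and was the only call among 28 members (3 higher and 1 lower without mutant array 1), against 6 higher and 4 lower adjusted over the list alone. Wnt4 and Rspo1 gave 0.61 and 0.90 (adjusted p = 0.0751 and 0.0873, 0.0457 and 0.0407 with the block), and the list's adjusted p was 0.579. No member passed among 14 hedgehog genes (0.672 for the list) and 15 Notch genes (0.824), or over those lists alone. Shh and the hedgehog target Gli1 gave 0.66 (0.33 without mutant array 1) and 0.36. With mutant array 1 left out, Gli1 and the hedgehog-binding protein gene Hhip gave 0.57 and 1.13 (adjusted p = 0.0291 and 0.0123). The Notch target Hey2 gave 0.48 (adjusted p = 0.280).

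The median epithelial gene was higher in each of the 3 mutants than in any control. All 23 tested epithelial genes had a positive log2 difference, with a median of 0.64. On their own 2 passed, 4 without mutant array 1 and 13 adjusted over the list alone. The 2 were the desmosome genes Dsp (0.56, standard error 0.084, adjusted p = 0.0249) and Pkp1 (0.78, standard error 0.14, adjusted p = 0.0429, 0.0556 with the block). Dsp lost the call as the mean of its probe sets (0.35, adjusted p = 0.151), and Pkp1 lost it with the lowest 50% of genes left out (0.0515) and with every probe set tested on its own (0.0542). The basal keratin gene Krt14 gave 0.94 (adjusted p = 0.0605, 0.0315 with the block) and Krt15 0.56 (0.0595). The list's adjusted p was 6.51e-11 with the preset and 0.382 with an estimated correlation. The array medians were 1.14, 0.55 and 0.345 in mutant arrays 1, 2 and 3 and between -0.069 and 0.096 in the controls. The order of the mutant arrays was thus the reverse of that for the sarcomere list. The arrays read RNA of whole samples, so list shifts between the genotypes do not tell tissue shares from expression within cells. Neither was tested.

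**Figure D3:**
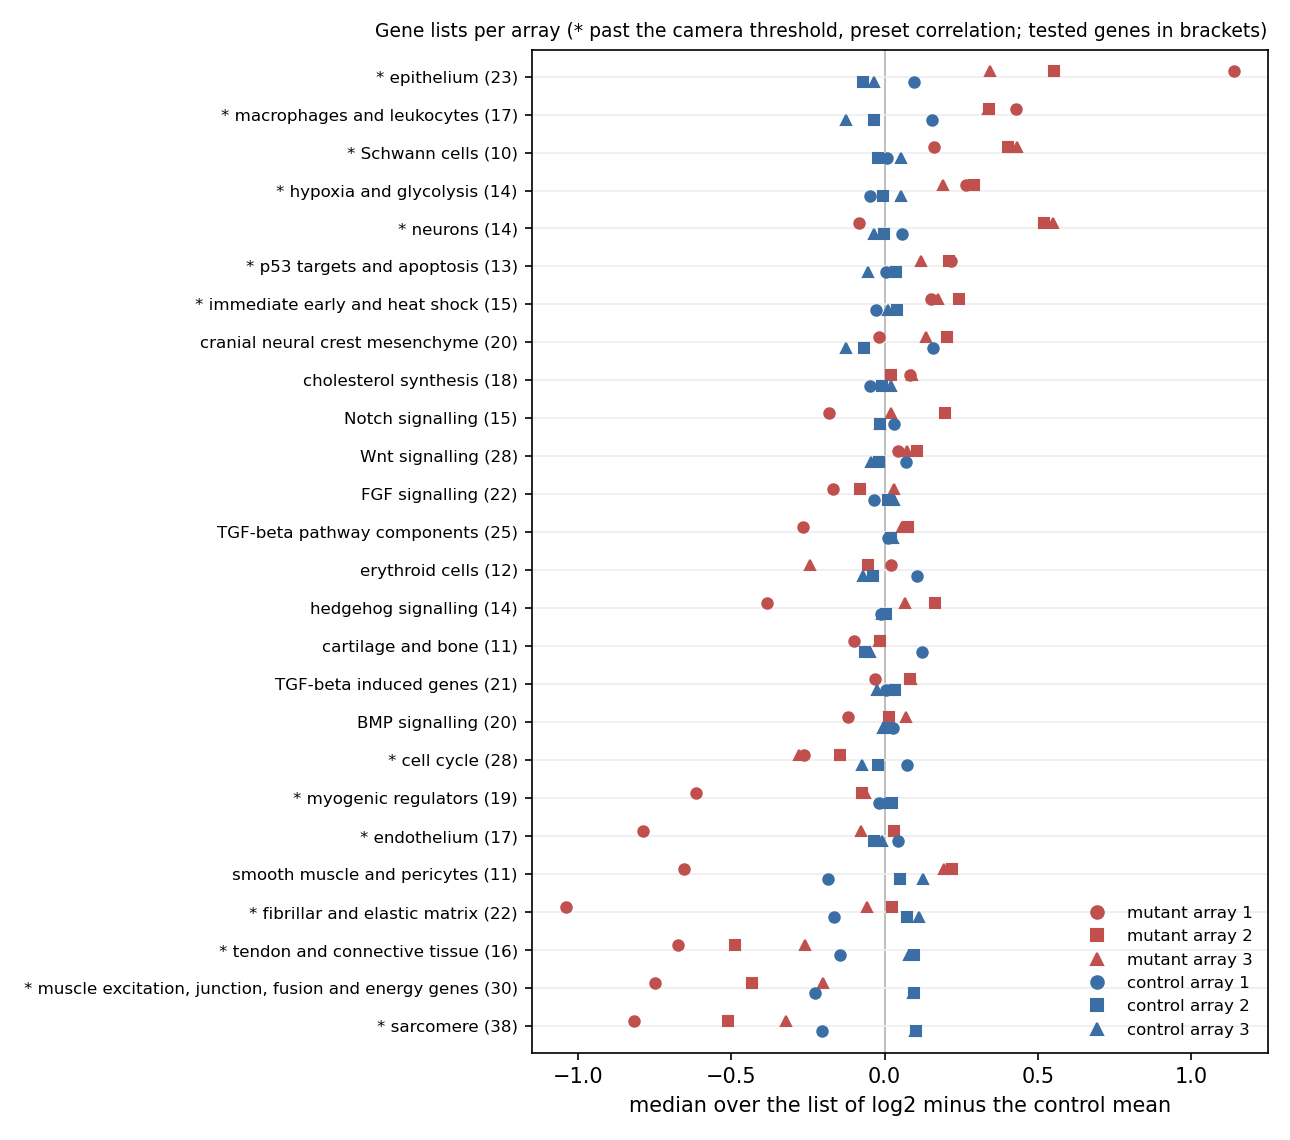
Median over each list of the log2 expression relative to the control mean of each gene, for the 6 arrays (colour for genotype, marker shape for replicate number), with the number of tested genes in brackets and a star where the list passed with camera's preset correlation. The epithelial medians of the mutants lie between 0.345 and 1.14, the sarcomere medians between -0.82 and -0.32, and none of the stars remains with an estimated correlation.

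Nerve markers gave few calls with all arrays. Of 10 Schwann cell genes 1 passed, Egfl8 (0.69, adjusted p = 0.0271), against 5 higher without mutant array 1 and 6 higher adjusted over the list alone, and Fabp7 gave 0.72 (adjusted p = 0.0621, 0.0351 with the block). The list's median was 0.32 (adjusted p = 0.00335, 0.0631 without mutant array 3, 0.382 with an estimated correlation). Of 14 neuronal genes 1 passed, Stmn2, a microtubule regulator of growing axons (1.07, adjusted p = 0.0272, 0.0707 as the mean of its probe sets), against 6 higher and 2 lower without mutant array 1 and 4 higher and 1 lower adjusted over the list alone. The neurofilament genes Nefl and Nefm gave 1.27 and 1.32 (adjusted p = 0.0599 and 0.0674, 0.0317 and 0.0701 with the block), whereas Dcx, a gene of migrating neurons, gave -1.34 (0.0736, 0.00887 with the block). The neuronal list's median was 0.22 (adjusted p = 0.0254), and 0.46 without mutant array 1. That call was lost without mutant array 2 (0.0644), without mutant array 3 (0.395), when each gene was the mean of its probe sets (0.111), with the lowest 50% of genes left out (0.217) and with an estimated correlation (adjusted p = 0.574). Mutant array 1 had a neuronal median of -0.084, and mutant arrays 2 and 3 had 0.52 and 0.55.

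Of 17 macrophage and leukocyte genes 14 had a positive log2 difference, and calls went in both directions. The complement genes C1qa, C1qb and C1qc rose by 1.05, 0.87 and 0.71 (adjusted p = 0.0152, 0.0482 and 0.0349), and Mrc1, encoding the mannose receptor, fell by 1.53 (adjusted p = 0.00775). The C1qb call was lost with the lowest 50% of genes left out (0.0569), with arrays centred on their median (0.0544), with quantile normalization (0.0576) and with every probe set tested on its own (0.0613). The other 13 of 17 members did not pass, and adjusted over the list alone 7 were higher and 1 lower. The median was 0.37 (adjusted p = 0.000264, 0.382 with an estimated correlation). Of 17 endothelial genes Lyve1 alone passed, against 2 lower without mutant array 1 and 2 lower adjusted over the list alone, and the tight junction gene Cldn5 gave -0.68 (adjusted p = 0.0555). The endothelial list shifted down with a median of -0.21 (adjusted p = 0.00335), a call lost without mutant array 1 (median -0.024, adjusted p = 0.210), with the lowest 50% of genes left out (0.195), with array quality weights (0.101) and with an estimated correlation (adjusted p = 0.574). Mutant array 1 had an endothelial median of -0.79, and mutant arrays 2 and 3 had 0.0305 and -0.0775. Of 12 erythroid genes none passed, 1 was lower without mutant array 1, 1 was lower adjusted over the list alone, and the list's adjusted p was 0.121, 0.0131 without mutant array 1, 0.0494 without control array 2 and 0.0425 with the sex covariate. With an estimated correlation it was 0.629, and 0.393 without mutant array 1, and fry gave 0.424 and 0.152. None of 11 smooth muscle and pericyte genes passed (adjusted p of the list 0.585), over all genes or adjusted over the list alone. Smtn, encoding the smooth muscle protein smoothelin, gave -0.56 (adjusted p = 0.198) and passed with the block (0.0397), and was at -0.37 without mutant array 1. The medians of this list were -0.66 in mutant array 1 and 0.22 and 0.195 in mutant arrays 2 and 3.

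Markers of the neural crest mesenchyme, which the deletion targets by design, did not pass with all arrays. None of 20 tested genes passed, 1 was higher and 1 lower without mutant array 1, 1 was higher adjusted over the list alone, and the list's adjusted p was 0.517. Barx1, a homeobox gene of jaw and tongue mesenchyme, gave 0.71 (adjusted p = 0.0779, 0.0201 with the block), and Tfap2b gave -0.92 (adjusted p = 0.162), or -0.57 without mutant array 1 (0.0302). Among 11 cartilage and bone genes Cnmd, encoding chondromodulin, and Col9a1, a cartilage collagen gene, rose by 1.61 and 0.87 (adjusted p = 0.0272 and 0.0283), and Dmp1, a dentin and bone matrix gene, fell by 1.32 (adjusted p = 0.0354). Col9a1 lost the call as the mean of its probe sets (0.57, adjusted p = 0.0683). Adjusted over the list alone 3 were higher and 1 lower. The cartilage and bone list did not shift (adjusted p = 0.824), and its median (-0.044) and mean (0.073) differed in sign.

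Most cell cycle genes had slightly lower values, and a few genes of the stress lists were higher. Of 28 cell cycle genes 25 were negative, with a median of -0.20, and 1 passed, Rrm2, a subunit gene of ribonucleotide reductase (fell by 0.66, adjusted p = 0.0232), against 2 lower without mutant array 1 and 5 lower adjusted over the list alone. Ccne1, encoding cyclin E1, gave -0.60 (adjusted p = 0.0599, 0.0375 with the block). The cell cycle list's adjusted p was 3.79e-07 (0.382 with an estimated correlation). Of 14 hypoxia and glycolysis genes 3 were higher, 5 adjusted over the list alone: Ndrg1 by 0.92, Egln3, an oxygen-sensing hydroxylase gene, by 0.74, and the glucose transporter gene Slc2a1 by 0.85 (adjusted p = 0.00911, 0.0238 and 0.0271). The mean of the Ndrg1 probe sets gave 0.58. That list's median was 0.22 (adjusted p = 0.000250, 0.382 with an estimated correlation). Of 13 p53 target and apoptosis genes 2 were higher, against 4 without mutant array 1 and 6 adjusted over the list alone. The 2 were Pmaip1, by the 2.64 given above, and Bbc3, encoding the pro-apoptotic protein Puma, by 0.56 (adjusted p = 0.0264). Fas and Phlda3 gave 0.74 and 0.64 (adjusted p = 0.0805 and 0.0527, 0.0201 and 0.0457 with the block). The p53 list's median was 0.16 and its mean 0.393, with 9 genes positive and 4 negative. Camera gave this list an adjusted p of 0.00433, 0.0513 without mutant array 3 and 0.382 with an estimated correlation. With all arrays the p53 list was the only one called by fry (adjusted p = 0.0241). Fry tests whether a list's genes shift one way on average, without comparing them with the other genes, whereas camera makes that comparison. The number of lists called by fry moved from 1 to 11 without mutant array 1 (10 higher, 1 lower) and to 3 without mutant array 3, and was 0 without mutant array 2 and without each of control arrays 1, 2 and 3.

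Of 15 immediate early and heat shock genes 2 were higher, over all genes and adjusted over the list alone: Egr2 by 1.16 and Junb by 0.64 (adjusted p = 0.0272 and 0.0354). Egr1 gave 0.66 (adjusted p = 0.167, 0.00261 without mutant array 1) and Hspa1b gave 0.57 (0.197, 0.0467 with the block). The list's median was 0.13 (adjusted p = 0.0313). Its call was lost without mutant array 2 (0.0858), mutant array 3 (0.107) or control array 1 (0.0712), without a filter on dim genes (0.0796), with the lowest 50% of genes left out (0.129), without genes shared between lists (0.1) and with an estimated correlation (adjusted p = 0.382). None of 18 cholesterol synthesis genes passed, over all genes or adjusted over the list alone, and the list did not shift (adjusted p = 0.579). In all, 14 of the 26 tested lists passed with the preset correlation, 7 higher and 7 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.382, and the numbers were 12 and 0 without mutant array 1. The 11 lists that fry called without that array were the myogenic regulators, which were lower (adjusted p = 0.0113), and, all higher, the TGF-beta, BMP and Notch lists given above, epithelium (0.0277), Schwann cells (0.0222), neurons (0.0208), immediate early and heat shock (0.0113), hypoxia and glycolysis (0.0433) and p53 targets (0.0222).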

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

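The comparisons use only probe sets with a single gene name. Among the 3567 other probe sets bright enough to be tested, which have no gene or several genes in the annotation used here, 11 passed an adjusted p of 0.05 when all 27874 such and named probe sets were tested together (limma). All 11 were higher in the mutants and 0 were lower. No explanation was tested for them.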

How the results depend on the processing

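The sex covariate, the estimated correlation without mutant array 1 and fry without 1 array were chosen after the data were seen, and where a value changed the cause was not tested unless stated. Against 292 changed genes (180 higher), there were 151 (95) with the lowest 50% of genes left out, 1034 (634) with array quality weights, 490 (283) with the replicate block, 135 (77) with the sex covariate and 549 (326) at an adjusted p under 0.1, a looser threshold. Leaving out 1 array, which leaves fewer samples, gave 16 to 670 (10 to 433 higher). The other alternatives gave 261 to 326 genes. Testing every probe set on its own gave 362 probe sets (203 higher), and several of these can read the same gene. Of 26 lists, 14 passed, against 0 with an estimated correlation, 0 with it and without mutant array 1, and 1 with fry. Leaving out 1 array gave 0 to 11 with fry, 11 without mutant array 1. The remaining alternatives gave 11 to 15. Of 55 called genes named, 10 kept the call under each alternative that tested them, 45 lost it without 1 array, and 37 lost it only in such fits or with the sex covariate. Leaving out the lowest 50% of genes removed 20 of the 55, 6 of these 10 among them, so they have no value there. None changed sign: of 860 values 654 kept the call and 206 lost it. Of 1241 values of named genes not called, 1135 stayed so, 99 passed with the same sign and 7 changed sign, of which Fgf4 passed. With the block 20 named genes gained the call and 1 lost it, each given beside its result. For called lists 215 of 280 values kept the call, 65 lost it and 0 changed direction.

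Among values that had not passed, some changed direction. Without 1 array the ranges were -0.30 to 0.014 for Tgfbr2, -0.35 to 0.30 for Tgfb2, -0.090 to 0.065 for Tgfbr1 and -0.013 to 0.60 for Tgfbr3. Fgf4 was -0.50 as the mean of its probe sets (adjusted p = 0.0206), Tgfb2 was 0.22 with array weights and Tgfbr1 was 0.012 with quantile normalization. For lists the values are means of log2 differences, and the direction is that of the test. Without 1 array they were -0.0984 to 0.0942 for TGF-beta components, -0.00044 to 0.15 for TGF-beta induced genes, 0.045 to 0.109 for BMP, -0.0963 to 0.187 for hedgehog, 0.00789 to 0.102 for Notch, -0.0114 to 0.164 for cartilage and bone and -0.258 to 0.127 for smooth muscle. With array weights TGF-beta components were at 0.0593, hedgehog at 0.148 and smooth muscle at 0.0175. With the sex covariate TGF-beta components were at 0.00982, hedgehog at 0.081 and cartilage at 0.0206. Without mutant array 1, with the estimated correlation and likewise with fry, the means were 0.0942, 0.187 and 0.127 for TGF-beta components, hedgehog and smooth muscle. For TGF-beta components fry turned the direction at a mean of -0.0301. TGF-beta induced genes were at -0.0959 with the lowest 50% left out and -0.00132 without shared genes, Notch at -0.00406 with the lowest 50% left out and 0.0183 with mean probe sets, and cartilage at 0.0587 with quantile normalization. Dim probe sets limit what can be seen: genes under 5.17 were not tested.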

Other observations

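The genes and gene groups in this part were chosen after their values were seen, and so were the tests of RNA degradation, of the epithelial share and of a reporter allele, whereas the count over splits, the macrophage marker tests and the tests of the other probe sets and neighbours of Gt(ROSA)26Sor were written down before those results.

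Some transcription factor genes outside the fixed lists were among the called genes, in both directions. Shox2, a homeobox gene of limb and palate mesenchyme, rose by 1.66 on the log2 scale (standard error 0.12, adjusted p = 0.00298 by limma), and so did Gata6 (1.23), the T-box genes Tbx18 (1.11) and Tbx22 (0.95), the latter known for its role in palate formation, and the homeobox gene Barx2 (0.75). The homeobox gene Dbx1 was lower (-2.10, adjusted p = 0.00298), and so were Pou3f3 (-1.59), the T-box gene Tbx15 (-1.59), Vgll2, a cofactor gene of skeletal muscle (-1.19), and Trps1 (-0.94). Of these 10 genes, Tbx18, Tbx22, Barx2, Tbx15 and Trps1 did not pass with the sex covariate (adjusted p between 0.0676 and 0.106). Aldh1a1, whose product makes retinoic acid, rose by 1.74 (adjusted p = 0.0249), and Cyp26b1, whose product degrades it, fell by 1.25 (adjusted p = 0.0150). Also higher were Krt17, a keratin gene (1.83, adjusted p = 0.0120), Col17a1, encoding a collagen of the hemidesmosome (0.94), and Lama3, encoding a laminin chain (0.84). None of these genes was part of a list tested for enrichment.

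Some genes best known from heart muscle were among the decreases: Myh6, encoding the alpha myosin heavy chain (-1.26, adjusted p = 0.00792), Lmod2, which lengthens actin filaments (-2.02, adjusted p = 0.0373, 0.0821 with the sex covariate), Nkx2-5, a cardiac homeobox gene (-1.09), Fhl2 (-0.99) and Tecrl (-0.90), beside Ankrd1. The 8 such genes noticed were all lower and 6 of them passed, with a median of -1.04. Csrp3 and Myl2, which did not pass, and Myl3 of the further genes are also members of the sarcomere list, so the heart group shares genes with it. Of 5 further heart genes tested, 4 were lower and 0 passed (limma), with a median of -0.29, but these are what was left once the called ones had been noticed, so they say nothing for or against a change of heart genes.

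Mutant array 1 stood apart, with epithelial genes higher by a median of 0.67 than in mutant arrays 2 and 3 and fibrillar matrix genes at a median of -0.81. RNA degradation is argued against by the control probe sets: the difference of the 3-prime and 5-prime actin signals was 0.821 in that array and between 0.675 and 0.928 in the other 5, and that for Gapdh was 0.0777 against 0.0397 to 0.369. A larger share of epithelium alone would lower all other cell types alike. Several lists were lower in that array: endothelium (-0.695), neurons (-0.61), smooth muscle (-0.597), sarcomere (-0.359) and Schwann cells (-0.276). The macrophage and erythroid lists were not, with medians of 0.0384 and 0.129. The macrophage median exceeded the matrix median by 0.85 (95% bootstrap interval over genes 0.453 to 1.3) and the erythroid median exceeded it by 0.94 (0.675 to 1.44). These intervals hold the spread over genes of 1 array against 2 and none between arrays, so a larger share of epithelium is not excluded. A more severe phenotype of that embryo, another dissection with fewer deep mesenchymal and muscle cells, or a slightly different stage may each account for it and were not tested.

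Gt(ROSA)26Sor had the highest fitted log2 difference, with a control mean of 4.53 under the filter value of 5.17, so its rank is uncertain, and the locus is a common site for reporter alleles. A change of the whole neighbourhood is argued against by the 10 nearest tested genes, with a median log2 difference of 0.042 (range -0.194 to 0.213), among them Setd5 at -0.194 and Thumpd3 at -0.0779. A reporter allele carried by the mutants might raise or alter this transcript, but 0 probe sets are named for a reporter sequence. Cross-hybridisation also stays open, since 0 other probe sets of the gene lay above the filter value. The values of 9.69, 6.98 and 7.57 in mutant arrays 1, 2 and 3 differ by more than those of any other leading gene.

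Macrophage genes went both ways: those noticed lower were Lyve1, Mrc1, F13a1 (-1.99) and Pf4 (-1.08), and those noticed higher included P2ry12 (1.55), Gpr34 (2.06, with a control mean of 5.03 under the filter value of 5.17) and Ctss (1.08), with Pf4, P2ry12 and Gpr34 not passing with the sex covariate. The hypothesis of fewer Lyve1-positive and more microglia-type macrophage transcripts was tested on further markers of either kind, 6 and 9 of which were tested genes. Their medians were 0.054 and 0.078, a difference of 0.024 (95% bootstrap interval -0.44 to 0.35, exact permutation p = 0.9 over genes, two-sided), but the called markers had been noticed first and left out, so this test excludes nothing. That exchange, a change in the number of all macrophages and an untested change of state within the same cells may each play a part, and all stay open.

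Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave 292 or more called genes, and the highest of the others gave 4. With 10 splits no share under 0.05 can be reached. That highest other split was the one that follows the sex-linked genes. Of the 4 splits that part all 3 numbered pairs, the other 3 gave at most 1 called gene.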
